A study of Callithrix jacchus with 6 samples.

How the data were processed

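Hippocampal single-cell suspensions of aged common marmosets were compared between 3 libraries from control animals given oxygen and 3 libraries from animals given sevoflurane, each for 6 h, as the sample labels state. Per the labels, the tissue was digested with collagenase, and the cells were cryopreserved before library preparation with 10x Genomics 3' chemistry. Base calls were made with CASAVA 1.8, counting was done with Cell Ranger and the authors' own clustering with Seurat, per the submitters' processing notes; the file header gives Cell Ranger 6.1.1. The deposited values were raw UMI counts per gene and cell barcode, as whole numbers with no normalisation, and all comparisons started from them. The genome build and the annotation release are not given in the sources used here. The features held 29320 genes: 15188 carried a symbol in the file, 1363 took one from the gene name table, and 12769 had none. No mitochondrially encoded gene was named among them, so the mitochondrial filter could not be applied.

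The 6 libraries held 8236, 7170 and 8167 barcodes (control replicates 1 to 3) and 8577, 7329 and 7103 barcodes (sevoflurane replicates 1 to 3). Their UMI totals were 45776166, 41664423, 42830458, 47886816, 41164947 and 43086546, and their median UMIs per barcode 3861, 3565, 3269, 3309, 4445 and 4843. Cells with at least 500 UMIs and at least 200 genes were kept; every deposited barcode met both. Doublets were scored per library with scrublet in scanpy 1.11.5. The automatic threshold of sevoflurane replicate 2 (0.567) marked 0.150% of its barcodes, so the median of the 6 automatic thresholds (0.190) was applied to every library, a choice made after the automatic values were seen. It marked 2238 barcodes, between 4.49% and 5.93% per library, and left 7866, 6846, 7783, 8182, 6985 and 6682 cells.

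Counts were scaled to 10000 per cell and log-transformed. Leiden clustering (igraph 0.11.9, resolution 1) used 15 neighbours on 30 principal components of 2000 variable genes, with no batch integration, and gave 34 clusters. Each cluster was scored on marker lists of cell types fixed before the data were examined. It took the name of the best list where the score reached 0.25, at least 3 markers were detected in at least 10% of its cells, and the second list stayed below a ratio of 0.6 to the best; these limits were set after the files were read. A cluster with none of its markers among its 10 leading genes and a median depth under 1/3 of that of its libraries stayed unnamed. This held for cluster 2 (1718 cells, median 836 UMIs, neuron markers at a score of 0.586). This named 23 clusters as 11 classes and left 11 clusters (2463 cells) unnamed, 3.75%, 3.27%, 9.55%, 5.93%, 6.18% and 4.25% of the 6 libraries. The microglia-like class (1837 cells, 1 cluster) was named on 3 detected markers, and none of its own markers stood among its 10 leading genes, which included INPP5D, TBXAS1 and RUNX1. Genes were compared in a class where each library held at least 20 of its cells, which gave microglia-like, astrocyte-like, oligodendrocyte-like, OPC-like, endothelial-like and GABAergic neuron-like cells. Glutamatergic neuron-like cells (18319 in 9 clusters) also met this limit, with 2304 to 3799 cells per library. They were not compared as a class because 2 of their clusters had a fibroblast marker and none of their own among their leading genes. Leaving them out departed from the plan and was decided after the clusters were seen. Of these cells, cluster 11 (1335 cells) was compared alone.

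Counts were summed per library and class, so that the library was the replicate. Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) after filterByExpr with TMM factors, and called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken from the fold change and its F value. FKBP5 was tested in every class, with p adjusted over the 6 classes besides microglia-like cells, and its response was compared between classes with limma 3.58.1 on differences of log2 CPM within libraries. An exact two-sided permutation test over the 20 arrangements of the labels, whose smallest p is 0.1, was used for class shares, for FKBP5 in microglia-like cells and for the share of cells with an FKBP5 UMI, where each cell was thinned to 1000 UMIs. Gene lists were tested with camera on voom values with its preset correlation, with an estimated correlation beside it, and with fry, adjusted within a class over the lists with at least 3 measured genes. There were 21 gene lists. The markers of the other cell types were tested the same way.

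The genes named in the text followed a rule written before the data were examined. FKBP5 was always named. In microglia-like cells these were up to 10 changed genes per direction with the largest fold change, a mean log2 CPM of at least 4 and no overlap between the groups, filled up to 5 by the smallest p as values. In the other classes and all cells together the limit was 5, filled up to 3. From each list that passed camera up to 4 members with the smallest p were named, and in microglia-like cells also from the glucocorticoid, inflammatory, homeostatic and immediate early lists whatever their test gave. Genes with no symbol in the features were counted and not named; exceptions are stated where they occur. Some genes that the rule took are counted but not reported here.

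The tests were tested on simulated data, counts drawn from the class means, library sizes and trended dispersions of these libraries with known changes put in. Genes were drawn independently, with no dispersion of their own and no library that stood apart, so the real tests may find fewer changes. In endothelial-like cells the real FKBP5 change of 4.16-fold had an edgeR adjusted p of 0.999 over all genes. At 4-fold, edgeR found 86% of the changed genes in microglia-like cells, 96% in astrocyte-like, 90% in oligodendrocyte-like, 90% in OPC-like, 83% in endothelial-like and 94% in GABAergic neuron-like cells, 93% in cluster 11 and 87% in all cells together. At 2-fold it found 37%, 56%, 46%, 59%, 13%, 62%, 50% and 31% in the same order. Among 50 unchanged lists of genes simulated independently of each other, 0 passed camera.

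Alternatives fixed before the data were examined were RLE factors, DESeq2 1.42.0, limma-voom, no filter on low counts, the replicate number as a block, leaving out each library, at least 1000 UMIs per cell, Leiden resolutions of 0.5 and 2, doublets kept, means of log-normalised values, camera with an estimated correlation and other thinning depths. Added after the data were seen were the oligodendrocyte-like class without the cluster that 1 library held over 80% of, the glucocorticoid list without FKBP5, the lists of endothelial-like cells without the library that stood apart in them, and a clustering without the 111 genes called in any class. In that last clustering all microglia-like cells but 1 in each of 3 libraries were found again. Other software was Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.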

Results

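The study counted RNA molecules in single cells of the hippocampus of common marmosets (Callithrix jacchus), aged animals per the series title, after 6 h of sevoflurane, an inhaled anaesthetic, or of oxygen alone as the control. There were 3 control and 3 sevoflurane libraries, each from a collagenase-digested and cryopreserved suspension. The libraries held between 7103 and 8577 cell barcodes and between 41164947 and 47886816 unique molecular identifiers (UMIs). Of 46582 barcodes, 44344 were kept after doublet removal, and 23 of 34 clusters were named as 11 cell classes by marker genes. The title names the question: whether sevoflurane raised FKBP5, a co-chaperone that lowers the sensitivity of the glucocorticoid receptor and is itself a target of that receptor, in microglia. The authors may have chosen FKBP5 on these samples, so its direction here cannot be counted as independent evidence. The labels do not say that the replicates came from separate animals, so every p-value measures the spread between these samples. Errors of expression levels are standard deviations over the 3 libraries of a group (n = 3), in CPM (UMI counts of the gene scaled to the total of the class in the library), and errors of log2 fold changes are standard errors from edgeR.

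The sevoflurane replicate 3 library stood apart in its neurons. It held 7 cells of neuron clusters 8, 9 and 17, where the other 5 libraries held 1513 to 3498, and 2275 cells of neuron clusters 21 and 22, where the others held 1 to 330. Its glutamatergic neuron-like cells had 18.3 CPM of ZBTB20, a transcription factor of hippocampal neurons, against 337 to 661 CPM in the other libraries. They also had 455 CPM of RORB, a transcription factor of cortical layer 4, against 6.49 to 62.5 CPM. These genes were chosen after their values were seen. Each count of changed genes was also computed without this library, as without each other one.

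In microglia-like cells, FKBP5 (ENSCJAG00000015725) rose from 407 ± 29.2 CPM in control libraries to 1928 ± 268 CPM after sevoflurane, a 4.77-fold change (log2 2.25 ± 0.18, n = 3 against 3, adjusted p = 0.000853). It was higher in each of the 3 sevoflurane libraries than in any control library, and its exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Of 7601 genes tested, 6 rose and 2 fell. DEPTOR, an inhibitor of the growth kinase mTOR, rose from 46.6 ± 12.2 to 143 ± 16.2 CPM (log2 1.64 ± 0.24, adjusted p = 0.0354). MRTFA, a coactivator of serum response factor, rose from 340 ± 18.0 to 899 ± 203 CPM (log2 1.41 ± 0.20, adjusted p = 0.0272). NCAM1, a cell adhesion molecule, rose from 804 ± 51.4 to 1917 ± 286 CPM (log2 1.26 ± 0.17, adjusted p = 0.0272). NAPEPLD, which makes N-acylethanolamines such as anandamide, fell from 99.2 ± 27.3 to 13.1 ± 4.37 CPM (log2 -2.79 ± 0.34, adjusted p = 0.0163).

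A further 2 changed genes of microglia-like cells had no symbol in the deposited table and were named after their values were seen. ELOVL5, a fatty acid elongase by the gene name table, rose from 196 ± 10.6 to 442 ± 46.7 CPM (log2 1.19 ± 0.17, adjusted p = 0.0272). The unnamed gene ENSCJAG00000066135 fell from 113 ± 14.0 to 17.2 ± 7.94 CPM (log2 -2.64 ± 0.30, adjusted p = 0.0150). Next by p among the lower genes, without passing, stood FCHSD2 at log2 -0.82 ± 0.15 (adjusted p = 0.154), NPFFR1 at -0.80 ± 0.16 (adjusted p = 0.239), CYTH4 at -2.09 ± 0.44 and MYO1F at -0.79 ± 0.17 (both adjusted p = 0.260). At unadjusted p under 0.05 there were 502 genes. No overlap between the groups was seen for 394 genes higher and 567 lower after sevoflurane, 12.6% of those tested, where chance alone gives 10%. The class held 157 to 523 cells and 347360 to 805142 UMIs per library. The count of 8 fell to 1 without control replicate 1 and without control replicate 3, in each case FKBP5. It was 3 without control replicate 2 (FKBP5, NAPEPLD and ENSCJAG00000059362, a gene with no symbol). Without sevoflurane replicate 1 it was 2 (FKBP5 and PCSK2). ENSCJAG00000059362 and PCSK2 were not among the 8. DEPTOR, MRTFA, NCAM1 and ELOVL5 thus passed in none of these runs. The count came to 22 with DESeq2, 114 with no filter on low counts and 2 on mean log-normalised values.

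**Figure D1:**
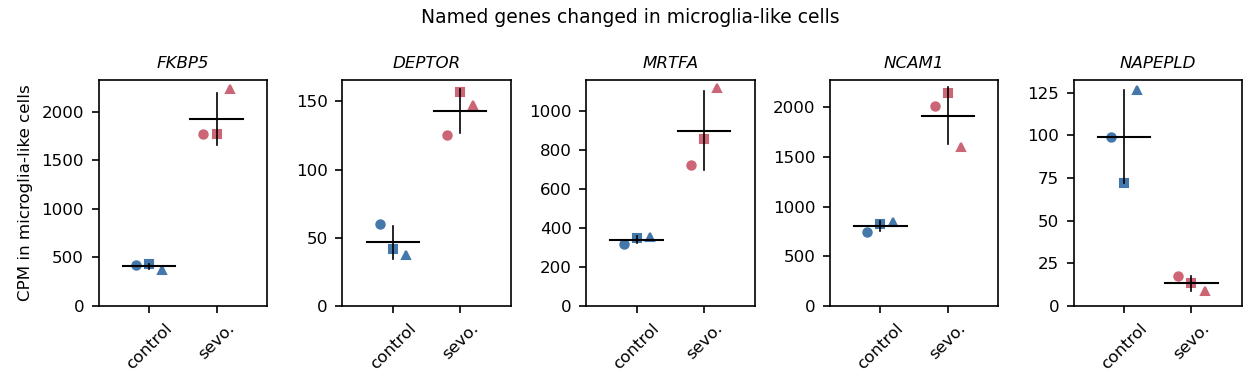
Expression in CPM (UMI counts scaled to the total of the class) of FKBP5, DEPTOR, MRTFA, NCAM1 and NAPEPLD in microglia-like cells; each point is 1 library, and bars give the mean ± SD of 3 control and 3 sevoflurane libraries. FKBP5 stood at 407 CPM in control and 1928 CPM in sevoflurane libraries, while NAPEPLD stood at 99.2 and 13.1 CPM.

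Among the gene lists fixed before the data were examined, the glucocorticoid response list rose in microglia-like cells (camera adjusted p = 3.17e-05; adjusted p = 0.351 with an estimated correlation). Of its 21 genes 8 were measured, and 7 had a positive fold change, with a median log2 of 0.84. Only FKBP5 passed over all genes, and 3 members were higher when adjusted over the list alone. DDIT4, an mTOR inhibitor induced by glucocorticoids, stood at log2 1.26 ± 0.33, ZBTB16 at 1.08 ± 0.38, IRS2 at 0.97 ± 0.41, TSC22D3 at 0.48, KLF9 at 0.37, GLUL at 0.71 and SGK1 at -0.19. By fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, the adjusted p was 0.110. Without FKBP5, a test added after the data were seen, the list rose at the preset correlation (camera adjusted p = 0.0206; adjusted p = 0.551 with an estimated correlation). OPC markers in the same cells had a median log2 of -0.32 (camera adjusted p = 0.177; fry adjusted p = 0.00578), and no marker list of another cell type passed camera. The number of lists that passed went from 1 to 4 without control replicate 3, to 3 without sevoflurane replicate 3 and to 0 with an estimated correlation.

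No other list passed in microglia-like cells. Of the inflammatory cytokine and NF-kB list, 4 of 25 genes were measured (camera adjusted p = 0.511), with the inflammasome gene NLRP3 at log2 0.40 ± 0.19, NFKB1 at 0.11 ± 0.18, IL18 at 0.29 ± 0.51 and RELB at 0.05 ± 0.37; none passed over the list alone. Of the homeostatic microglia list, 11 of 18 genes were measured (camera adjusted p = 0.102; 0.551 with an estimated correlation), and 1 was higher when adjusted over the list alone. TGFBR2, a receptor of the TGF-beta signal that maintains microglia, stood at log2 0.71 ± 0.18, CST3 at 0.91 ± 0.48, SLC2A5 at 0.32 ± 0.20 and GPR34 at 0.64 ± 0.40. Interferon-stimulated genes had a camera adjusted p of 0.757, the complement and phagocytosis list 0.964, heat shock and chaperones 0.898 and ribosomal proteins 0.174. Fewer than 3 immediate early genes were measured in this class, so that list was not tested in it. The microglia markers themselves had a median log2 of 0.07 over 6 measured genes (camera adjusted p = 0.761).

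The share of microglia-like cells with at least 1 FKBP5 UMI, with every cell thinned to 1000 UMIs, was 28.1%, 27.3% and 26.9% in the control and 77.1%, 74.0% and 77.6% in the sevoflurane libraries. Exact Clopper-Pearson 95% intervals spanned 21.9% to 34.0% over the control and 68.1% to 83.8% over the sevoflurane libraries. The means were 27.4 ± 0.601% and 76.2 ± 1.93% (SD, n = 3), a difference of 48.8 percentage points (exact permutation p = 0.1, the smallest possible). Thinning left out 26 control and 63 sevoflurane cells below 1000 UMIs, and the median depth before thinning lay between 1507 and 2102 UMIs. Without thinning the means were 46.1 ± 2.19% and 88.4 ± 4.01%. As a background, the thinned share in GABAergic neuron-like cells was 1.67 ± 0.439% in control and 2.51 ± 0.633% in sevoflurane libraries, at median depths of 5435 to 8673 UMIs.

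Beyond microglia, FKBP5 also rose in 4 of 6 other tested classes when its p was adjusted over those 6 classes. In endothelial-like cells it rose 4.16-fold, from 122 ± 23.0 to 479 ± 197 CPM (log2 2.06 ± 0.39, adjusted p = 0.00151). In oligodendrocyte-like cells it rose 2.27-fold, from 42.8 ± 4.42 to 96.9 ± 14.0 CPM (log2 1.18 ± 0.16, adjusted p = 0.000483), and in astrocyte-like cells 2.03-fold, from 81.0 ± 24.0 to 162 ± 15.7 CPM (log2 1.02 ± 0.22, adjusted p = 0.00209). In oligodendrocyte precursor-like (OPC-like) cells it rose 1.62-fold, from 46.7 ± 6.47 to 75.1 ± 6.88 CPM (log2 0.69 ± 0.19, adjusted p = 0.00477). It stood at log2 0.40 ± 0.24 in GABAergic neuron-like cells (16.8 against 21.7 CPM, adjusted p = 0.164) and at -0.07 ± 0.28 in glutamatergic neuron cluster 11 (43.4 against 41.8 CPM, adjusted p = 0.799). Adjusted over all genes by edgeR, FKBP5 passed in none of these 6 classes, and the lowest such value was 0.117, in oligodendrocyte-like cells. By DESeq2 it passed over all genes in astrocyte-like (adjusted p = 0.0216), oligodendrocyte-like (adjusted p = 0.000153) and endothelial-like cells (adjusted p = 0.0198), and in the same 3 classes by edgeR with no filter on low counts. In GABAergic neuron-like cells it passed over the 6 classes at log2 0.65 without control replicate 1 and 0.86 at clustering resolution 0.5. In cluster 11 the sign turned without control replicate 2 (log2 0.036) and without sevoflurane replicate 3 (log2 0.23). On mean log-normalised values, a scale on which differences are not log2 fold changes, it passed in GABAergic neuron-like cells at 0.0582 and its sign turned in cluster 11 at 0.0476.

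The FKBP5 response of microglia-like cells was compared with that of each other class within libraries, with p adjusted over the 6 comparisons. Adjusted over all genes none of them passed (0.285 to 0.981), and no gene differed in any comparison. It exceeded that of astrocyte-like cells by log2 1.17 ± 0.29 (limma adjusted p = 0.00410), that of oligodendrocyte-like cells by 1.07 ± 0.31 (adjusted p = 0.00918) and that of OPC-like cells by 1.56 ± 0.30 (adjusted p = 0.00180). Against GABAergic neuron-like cells the difference was 1.83 ± 0.40 (adjusted p = 0.00270), and against cluster 11 it was 2.31 ± 0.45 (adjusted p = 0.00180). Against endothelial-like cells the difference of 0.32 ± 0.40 did not pass (adjusted p = 0.440), and its sign turned without sevoflurane replicate 1 (-0.019).

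**Figure D2:**
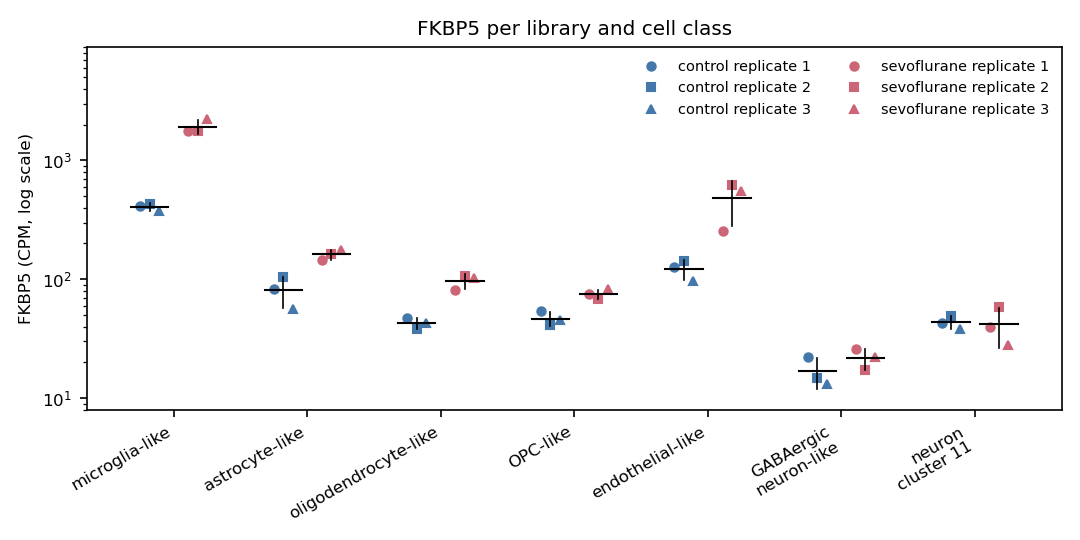
FKBP5 in CPM (UMI counts scaled to the total of the class, log axis) in each tested cell class; each point is 1 library, and bars give the mean ± SD of 3 control and 3 sevoflurane libraries. The highest means after sevoflurane were those of microglia-like cells (1928 CPM) and endothelial-like cells (479 CPM).

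The glucocorticoid response list rose in 3 further classes. In astrocyte-like cells 14 of its 21 genes were measured and 12 had a positive fold change (median log2 0.79; camera adjusted p = 1.86e-07; adjusted p = 0.0727 with an estimated correlation; fry adjusted p = 0.00208). None passed over all genes, and 5 were higher and 1 lower when adjusted over the list alone. IRS2, an insulin receptor substrate, stood there at log2 1.21 ± 0.20, DDIT4 at 1.16 ± 0.21, CRISPLD2 at 1.16 ± 0.28, TSC22D3 at 1.38 ± 0.52, KLF9 at 0.93 ± 0.29 and SGK1 at -0.88 ± 0.28. In oligodendrocyte-like cells 10 of 11 measured genes were positive (median log2 0.70; camera adjusted p = 1.84e-07; adjusted p = 0.262 with an estimated correlation; fry adjusted p = 0.0830). There 5 were higher over the list alone and none over all genes, with the transcription factors ZBTB16 at log2 1.08 ± 0.16 and KLF9 at 1.37 ± 0.34, DDIT4 at 0.93 ± 0.24 and GLUL at 0.96 ± 0.18.

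In endothelial-like cells 9 of 10 measured genes of the glucocorticoid list were positive (median log2 0.93; camera adjusted p = 0.000745; adjusted p = 0.366 with an estimated correlation; fry adjusted p = 0.476), and 1, FKBP5, was higher over the list alone. NFKBIA, the inhibitor of NF-kB, stood at log2 1.52 ± 0.71, ZBTB16 at 1.01 ± 0.47 and KLF9 at 0.91 ± 0.44. Sevoflurane replicate 2 stood apart in endothelial-like cells, with 53 cells and a highest correlation of 0.750 with any other library, against 0.912 or more for the others. Its NFKBIA level was 474 CPM, while the other sevoflurane libraries had 68.4 and 104 CPM and the controls 60.8 to 105 CPM. Without that library, a test added after the data were seen, the list still rose there at the preset correlation (camera adjusted p = 0.000540; adjusted p = 0.480 with an estimated correlation). The list did not pass in OPC-like cells (10 genes, adjusted p = 0.202), GABAergic neuron-like cells (12 genes, adjusted p = 0.915) or cluster 11 (7 genes, adjusted p = 0.209). In cluster 11 SGK1, a kinase of the same list, fell (log2 -1.08 ± 0.21, adjusted p = 0.0481 over all genes), and 3 members were higher and 1 lower when adjusted over the list alone. Without FKBP5 the list rose in the same 4 classes at the preset correlation, with camera adjusted p of 0.0206 in microglia-like, 4.73e-06 in astrocyte-like, 1.31e-05 in oligodendrocyte-like and 0.0215 in endothelial-like cells. None of these calls held with an estimated correlation, where the adjusted p was 0.551, 0.0746, 0.251 and 0.509 in the same order.

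**Figure D3:**
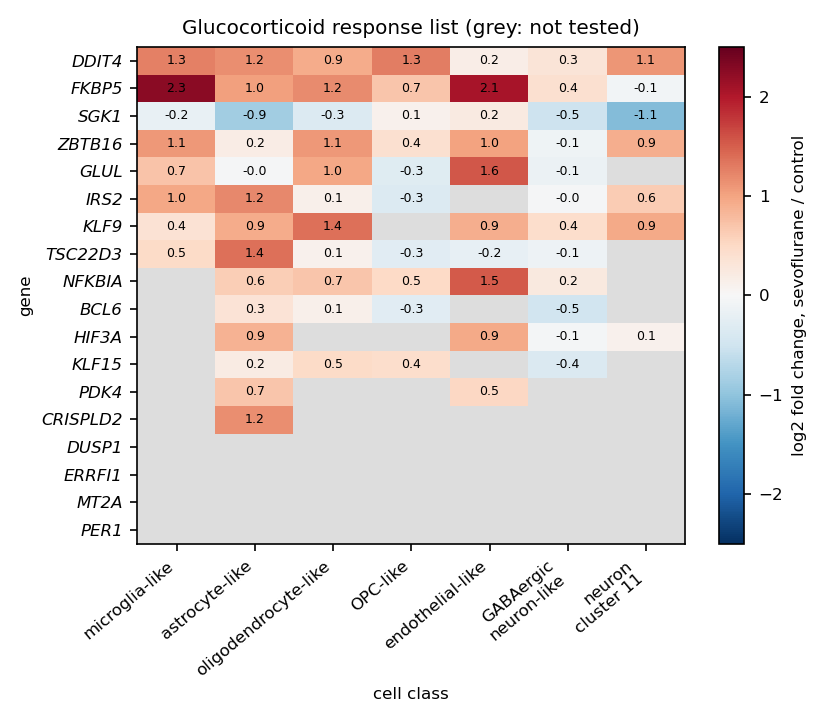
Log2 fold change, sevoflurane against control (3 libraries each), of genes of the glucocorticoid response list in each tested class. Colour gives the log2 fold change, and grey marks genes that were not tested in that class. FKBP5 ranges from -0.07 in cluster 11 to 2.25 in microglia-like cells.

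In astrocyte-like cells 2 genes fell and none rose, of 11114 tested. TNC, the matrix glycoprotein tenascin C, fell from 48.9 ± 5.45 to 4.79 ± 1.55 CPM (log2 -3.34 ± 0.27, adjusted p = 0.00403). PDE3A, a cyclic nucleotide phosphodiesterase, fell from 122.7 ± 25.1 to 23.4 ± 2.24 CPM (log2 -2.37 ± 0.20, adjusted p = 0.00403). By value, TFCP2L1 stood at log2 0.85 ± 0.15 and MAMDC2 at -1.50 ± 0.22. The marker GFAP, an intermediate filament of astrocytes, stood at -0.79 (adjusted p = 0.284). Neuron markers in these cells had a median log2 of -0.20 and ependymal markers of -0.46 (camera adjusted p = 0.0918 for both). At unadjusted p under 0.05 there were 748 genes, and 572 higher and 786 lower genes showed no overlap, 12.2% of those tested against 10% by chance. The count of 2 went to 0 without sevoflurane replicate 1 and to 4 without sevoflurane replicate 3; it was 37 with DESeq2 and 163 with no filter on low counts.

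A further 4 lists moved in astrocyte-like cells by camera, none of them with an estimated correlation. Interferon-stimulated genes rose, with 11 of 12 measured genes positive (median log2 0.35, camera adjusted p = 2.04e-05, and 0.0746 with an estimated correlation, fry adjusted p = 0.00286). Over the list alone 3 were higher, among them IFIT1 at log2 1.25 ± 0.34 and IFI6 at 1.37 ± 0.38. HERC5, at 0.38 ± 0.23, was not. The complement and phagocytosis list rose on 3 measured genes (median log2 0.39, camera adjusted p = 0.0103, and 0.316 with an estimated correlation). Of these, 2 were higher over the list alone: complement component C3 at log2 1.10 ± 0.40 and a gene not named here. The phagocytic receptor MERTK, at 0.23 ± 0.19, was not. Heat shock and chaperone genes fell over 17 measured genes (median log2 -0.28, camera adjusted p = 0.00157, and 0.563 with an estimated correlation). Of these, 2 were lower over the list alone: the steroid receptor chaperone FKBP4 at log2 -1.91 ± 0.44 and a gene not named here. CRYAB at -0.48 ± 0.22, HSPH1 at -0.58 ± 0.28 and CHORDC1 at -0.48 ± 0.29 were not. Cholesterol synthesis genes rose, with 15 of 19 positive (median log2 0.26; adjusted p = 0.0103; adjusted p = 0.563 with an estimated correlation) and 0 over the list alone; MSMO1 stood at log2 0.82 ± 0.27, HMGCS1 at 0.90 ± 0.32 and SQLE at 0.51 ± 0.24. No gene of these 4 lists passed over all genes.

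In oligodendrocyte-like cells NAV2, a cytoskeletal protein of neurite growth, rose from 134 ± 19.9 to 445 ± 73.4 CPM (log2 1.73 ± 0.17, adjusted p = 0.0310). CPQ, a secreted carboxypeptidase, fell from 147 ± 13.1 to 49.7 ± 4.68 CPM (log2 -1.56 ± 0.14, adjusted p = 0.0310). These were the only changed genes of 11679 tested. By value, NDRG1 stood at log2 0.94 ± 0.10 (adjusted p = 0.0681), GAP43 at 0.90 ± 0.12, RELN at -1.27 ± 0.15 and GPC6 at -0.85 ± 0.11. Astrocyte markers in these cells had a median log2 of -0.24 and ependymal markers of -1.08 (camera adjusted p = 0.0659 for both). At unadjusted p under 0.05 there were 912 genes, and 747 higher and 834 lower genes showed no overlap, 13.5% against 10% by chance. The count of 2 was 0 without any single control replicate and without sevoflurane replicate 1, and 1 (NAV2) without sevoflurane replicate 2. Cluster 7 of this class had 1013 of its 1154 cells in sevoflurane replicate 3; without that cluster, a test added after the data were seen, CPQ stayed and NAV2 did not (adjusted p = 0.175). The count was 44 with DESeq2, 60 with no filter on low counts and 1 (CPQ) on mean log-normalised values.

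A further 3 lists moved in oligodendrocyte-like cells by camera, again none with an estimated correlation and none with a member past the threshold over all genes or over the list alone. Immediate early genes fell, with 0 of 6 positive (median log2 -0.48; adjusted p = 0.0157; adjusted p = 0.357 with an estimated correlation): the nuclear receptors NR4A3 and NR4A2 stood at log2 -2.0 ± 0.63 and -0.77 ± 0.28, IER3 at -0.46 ± 0.41 and FOSL2 at -0.50 ± 0.54. Myelin genes fell, with 1 of 13 positive (median log2 -0.12; adjusted p = 0.0157; adjusted p = 0.490 with an estimated correlation): FA2H, which makes the hydroxylated fatty acids of myelin lipids, stood at log2 -0.36 ± 0.12, MAL at -0.39 ± 0.19, GAL3ST1 at -0.42 ± 0.24 and UGT8 at -0.22 ± 0.16. Circadian clock genes rose, with 11 of 13 positive (median log2 0.15; adjusted p = 0.0284; adjusted p = 0.412 with an estimated correlation): the repressors CRY2 and NR1D1 stood at log2 0.64 ± 0.20 and 0.65 ± 0.22, NR1D2 at 0.40 ± 0.19 and BHLHE41 at 0.61 ± 0.37.

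In OPC-like cells 2 genes rose and 1 fell, of 9111 tested. IGFBP5, a secreted protein that binds insulin-like growth factors, rose from 90.8 ± 18.9 to 212 ± 18.1 CPM (log2 1.25 ± 0.16, adjusted p = 0.0135). EEF2K, the kinase that slows translation elongation, rose from 190 ± 22.2 to 390 ± 76.5 CPM (log2 1.05 ± 0.16, adjusted p = 0.0441). HDAC9, a class IIa histone deacetylase, fell from 1173 ± 209 to 338 ± 130 CPM (log2 -1.80 ± 0.21, adjusted p = 0.0122). By value, RTKN stood at log2 1.03 ± 0.16 (adjusted p = 0.0574), SLC24A3 at -0.72 ± 0.13 and KCNN3 at -1.78 ± 0.33. Heat shock and chaperone genes fell, with 0 of 15 positive and none past the threshold over all genes or over the list alone (median log2 -0.25; camera adjusted p = 0.0410; adjusted p = 0.858 with an estimated correlation); HSPA4L stood at log2 -0.58 ± 0.23, CHORDC1 at -0.64 ± 0.31, HSPH1 at -0.50 ± 0.31 and CRYAB at -0.49 ± 0.46. Astrocyte markers fell in the same cells (median log2 -0.45; camera adjusted p = 0.00585; adjusted p = 0.148 with an estimated correlation). At unadjusted p under 0.05 there were 572 genes, and 498 higher and 573 lower genes showed no overlap, 11.8% against 10% by chance. The count of 3 was 1 (IGFBP5) without control replicate 1, 1 (EEF2K) without sevoflurane replicate 1, 0 without control replicate 2, control replicate 3 or sevoflurane replicate 2, and 10 without sevoflurane replicate 3. It was 17 with DESeq2 and 102 with no filter on low counts.

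In endothelial-like cells edgeR called 0 of 6598 genes changed, with 296 at unadjusted p under 0.05. DESeq2 called 1 gene, FKBP5, and limma-voom called 0; with no filter on low counts edgeR called 235. By value, PCSK6, a proprotein convertase, stood at log2 1.93 ± 0.44, RPS6KA5 at 1.20 ± 0.28, C1orf54 at -1.78 ± 0.38, DNM3 at -0.99 ± 0.23 and the focal adhesion protein VCL at -1.62 ± 0.39. Blood-brain barrier genes fell by camera, with 2 of 13 positive (median log2 -0.50; adjusted p = 6.88e-05; adjusted p = 0.509 with an estimated correlation): the endothelial cadherin CDH5 stood at log2 -1.22 ± 0.31, CAV1 at -1.25 ± 0.46, the glucose transporter SLC2A1 at -0.77 ± 0.29 and the lipid transporter MFSD2A at -1.08 ± 0.49. Heat shock and chaperone genes also fell, with 1 of 11 positive (median log2 -0.52; adjusted p = 0.000508; adjusted p = 0.655 with an estimated correlation), with HSPA4L at log2 -0.76 ± 0.38, HSP90AA1 at -0.60 ± 0.36, HSPH1 at -0.76 ± 0.46 and CHORDC1 at -0.52 ± 0.40. No gene of either list passed over all genes or over the list alone. The class's own endothelial markers fell alongside (median log2 -0.37, camera adjusted p = 0.00178, and 0.480 with an estimated correlation). That marker list shares CLDN5, CDH5 and ABCB1 with the blood-brain barrier list, so its fall is not separate from that of the barrier genes. No overlap was seen for 242 higher and 463 lower genes, 10.7% against 10% by chance. Without sevoflurane replicate 2, which stood apart in this class, the number of lists that passed went from 3 to 5. Blood-brain barrier genes (camera adjusted p = 0.00378) and heat shock genes (adjusted p = 0.000331) passed there again, and immediate early genes (adjusted p = 0.00535) and ribosomal proteins (adjusted p = 6.34e-10) fell as well; with an estimated correlation the lowest adjusted p was 0.480. The class held 53 to 192 cells and 195416 to 599695 UMIs per library.

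In GABAergic neuron-like cells edgeR called 0 of 13110 genes changed, with 1497 at unadjusted p under 0.05. The genes nearest the threshold, all at adjusted p = 0.0503, included ABCA13 at log2 1.59 ± 0.19, AGBL3 at 1.71 ± 0.22, KCNE2 at 1.08 ± 0.14, SHC3 at -0.85 ± 0.11, ANKRD55 at -1.71 ± 0.22 and the synaptic scaffold SHANK1 at -0.85 ± 0.11. The count was 206 with DESeq2, 12 with limma-voom, 15 with RLE factors, 254 with no filter on low counts, 1 at clustering resolution 0.5, 15 at resolution 2, 15 on mean log-normalised values and 21 without sevoflurane replicate 3. Cholesterol synthesis genes rose by camera, with 21 of 21 positive (median log2 0.57; adjusted p = 2.06e-08; adjusted p = 0.626 with an estimated correlation) and 2 higher over the list alone. Those 2 were mevalonate kinase MVK, at log2 0.76 ± 0.16, and a gene not named here. ACAT2 at 0.96 ± 0.29 and MSMO1 at 1.00 ± 0.33 were not higher over the list alone. Heat shock and chaperone genes fell, with 0 of 17 positive and 0 over the list alone (median log2 -0.36; adjusted p = 0.00628; adjusted p = 0.731 with an estimated correlation), with HSPA4 at log2 -0.38 ± 0.13, HSPH1 at -0.60 ± 0.27, CHORDC1 at -0.60 ± 0.30 and HSP90AA1 at -0.36 ± 0.21. Markers of oligodendrocytes (median log2 -0.55; camera adjusted p = 0.0284), astrocytes (median log2 -0.62; adjusted p = 0.0335) and ependymal cells (median log2 -0.55; adjusted p = 0.0335) fell in the same cells, each with adjusted p = 0.423 with an estimated correlation. No overlap was seen for 1043 higher and 1241 lower genes, 17.4% against 10% by chance.

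Among glutamatergic neuron-like cells, cluster 11 (leading genes HS3ST4, DPP10, KIAA1217 and GRIK3) was the only cluster with at least 20 cells in every library, with 90 to 406. In it 29 genes rose and 69 fell, of 9958 tested; 17 of these had no symbol. TNNI3K rose from 6.37 ± 3.56 to 36.8 ± 2.41 CPM (log2 2.45 ± 0.33, adjusted p = 0.0190), AGBL3 from 11.98 ± 4.83 to 51.4 ± 13.5 CPM (log2 2.19 ± 0.34, adjusted p = 0.0263) and the annexin ANXA4 from 15.8 ± 6.88 to 63.1 ± 5.63 CPM (log2 2.10 ± 0.27, adjusted p = 0.0190). The growth factor TGFA rose by log2 1.87 ± 0.35 (adjusted p = 0.0481) and SIDT1 by 1.53 ± 0.26 (adjusted p = 0.0340). ETV5, a transcription factor downstream of growth factor signals, fell from 141 ± 90.7 to 14.4 ± 7.23 CPM (log2 -3.10 ± 0.49, adjusted p = 0.0277), and HS3ST5, a heparan sulfate sulfotransferase, fell from 134 ± 39.1 to 31.2 ± 2.16 CPM (log2 -2.09 ± 0.23, adjusted p = 0.0176). ARHGAP8 fell with log2 -2.22 ± 0.30 (adjusted p = 0.0190), SYT17 with -2.17 ± 0.33 (adjusted p = 0.0263) and MKX with -2.07 ± 0.32 (adjusted p = 0.0270). DEPTOR, also changed in microglia-like cells, rose here (log2 1.30 ± 0.24, adjusted p = 0.0415), and HDAC9, also changed in OPC-like cells, fell (log2 -0.81 ± 0.13, adjusted p = 0.0340); no other changed gene was shared between classes.

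No gene list passed camera in cluster 11, while astrocyte markers fell in it (median log2 -0.86; camera adjusted p = 0.0179; adjusted p = 0.202 with an estimated correlation). The astrocyte marker SLC1A2, named after its values were seen, fell from 427 to 195 CPM (log2 -1.10 ± 0.16, adjusted p = 0.0245). The list members TIMP2 (log2 -1.42 ± 0.20, adjusted p = 0.0212) and CRY1 (log2 -1.27 ± 0.24, adjusted p = 0.0447) fell and NR1D2 (log2 0.95 ± 0.16, adjusted p = 0.0340) rose, named likewise. At unadjusted p under 0.05 there were 1307 genes, and 756 higher and 1139 lower genes showed no overlap, 19.0% against 10% by chance. The count of 98 was 28 without control replicate 1, 13 without control replicate 2, 21 without control replicate 3, 0 without sevoflurane replicate 1, 18 without sevoflurane replicate 2 and 230 without sevoflurane replicate 3. It was 242 with DESeq2 and 748 with no filter on low counts.

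The remaining lists passed in no class. Their lowest camera adjusted p over the 7 classes was 0.0646 for autophagy and lysosome genes, 0.0732 for disease-associated microglia genes, 0.0802 for the unfolded protein response, 0.105 for p53 and apoptosis and 0.118 for ribosomal proteins. It was 0.154 for glycolysis and hypoxia, 0.316 for reactive astrocyte genes, 0.374 for oxidative phosphorylation and 0.706 for antioxidant genes. Of the MHC class II genes fewer than 3 were measured in every class.

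With all cells of a library summed, edgeR called 0 of 19236 genes changed, with 1942 at unadjusted p under 0.05; DESeq2 called 427 and limma-voom 1, a gene with no symbol. FKBP5 stood at 51.1 ± 10.4 CPM in control and 85.5 ± 7.76 CPM in sevoflurane libraries (log2 0.75 ± 0.16, adjusted p = 0.330; 0.0135 with DESeq2). RELN, the secreted protein reelin, was nearest the threshold at log2 -1.35 ± 0.11 (adjusted p = 0.0782). AGBL3 stood at 1.57 ± 0.21, FBXL13 at 0.59 ± 0.10, SDF4 at 0.57 ± 0.10, RP1 at -2.84 ± 0.33 and TMEM47 at -0.98 ± 0.13. No overlap was seen for 1414 higher and 1674 lower genes, 16.1% against 10% by chance. These sums also move with the shares of the cell classes.

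The make-up of the suspensions was compared by the share of each class among kept cells, glutamatergic neuron-like cells left aside because 2 of their clusters (9 and 24) had a marker of another class and none of their own among their leading genes. As named, that class made up 36.8 ± 5.66% in control and 46.2 ± 8.05% in sevoflurane libraries (exact permutation p = 0.2). Its difference of 9.34 percentage points was larger than that of any class compared. Shares are parts of 1 total, so a lower share of another class need not mean fewer of those cells. Astrocyte-like cells made up 14.0 ± 3.25% in control and 7.99 ± 0.546% in sevoflurane libraries (n = 3 each), and ependymal-like cells 4.73 ± 1.75% and 0.820 ± 0.607%; both had an exact permutation p of 0.1, the smallest possible, and 0.55 after adjustment over all 11 classes. Microglia-like cells made up 3.96 ± 0.626% and 4.22 ± 2.04% (exact p = 0.8). Oligodendrocyte-like cells stood at 17.7% and 18.9%, GABAergic neuron-like cells at 9.11% and 8.17%, OPC-like cells at 4.82% and 3.94% and endothelial-like cells at 1.90% and 1.45%. Fibroblast-like cells stood at 1.24% and 0.667%, border macrophage-like cells at 0.104% and 0.138% and choroid plexus-like cells at 0.0779% and 2.06%. By the exact test no class could pass 0.05 with 3 libraries against 3. With 1 library left out the difference ran from -7.78 to -4.56 percentage points in astrocyte-like and from -4.90 to -3.24 in ependymal-like cells, while in every other class compared it moved by over 1.5 times. Without turning it ran from -1.16 to -0.349 in OPC-like, -0.841 to -0.0983 in endothelial-like, -0.844 to -0.113 in fibroblast-like and 0.00357 to 0.0587 in border macrophage-like cells. The sign of the difference turned in microglia-like cells without control replicate 1 (-0.0378 percentage points) or sevoflurane replicate 1 (-0.830), in GABAergic neuron-like cells without sevoflurane replicate 1 (0.264) or 2 (0.786), in oligodendrocyte-like cells without control replicate 3 (-0.964), in choroid plexus-like cells without sevoflurane replicate 1 (-0.0636), and in border macrophage-like cells with doublets kept (-0.104) or at resolution 2 (-0.0873).

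**Figure D4:**
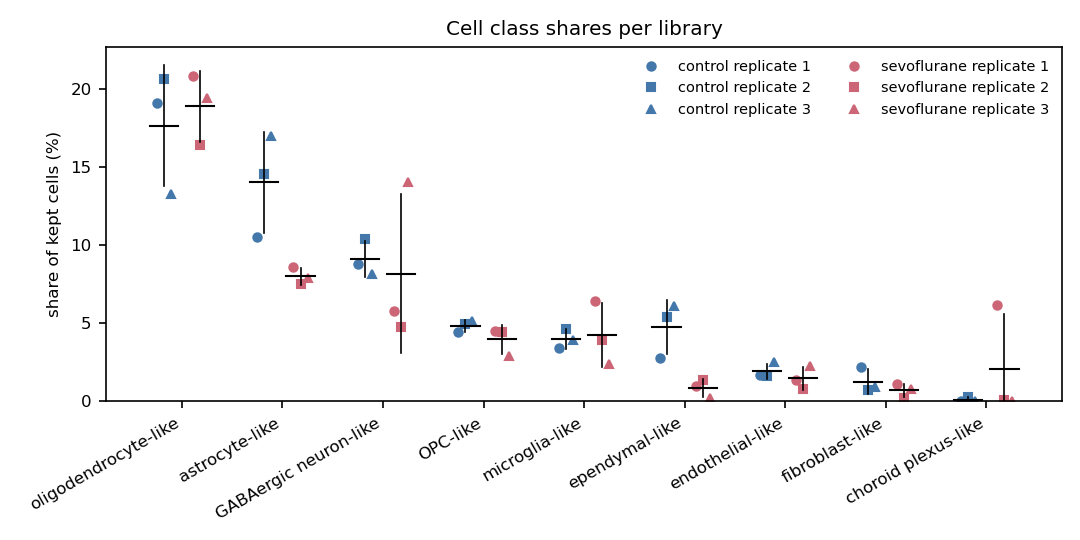
Share of kept cells (percent) of each named cell class but border macrophage-like and glutamatergic neuron-like cells; each point is 1 library, and bars give the mean ± SD of 3 control and 3 sevoflurane libraries. Astrocyte-like and ependymal-like cells are the classes in which all control libraries lie above all sevoflurane libraries.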

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

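The tests of free RNA, of depth, of dissociation stress, of the other splits and of the count of neuron clusters 21 and 22 were chosen only after the results were seen. The glucocorticoid list without FKBP5 was also added after the data were seen, though its prediction was written before its value was computed.

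The FKBP5 response to sevoflurane differed between cell classes by a test of the difference itself: microglia-like cells exceeded astrocyte-like cells by log2 1.17, oligodendrocyte-like cells by 1.07, OPC-like cells by 1.56, GABAergic neuron-like cells by 1.83 and cluster 11 by 2.31, with p adjusted over the 6 comparisons and none passing over all genes. In a class that no comparison of genes used, choroid plexus-like cells made up 6.15% of sevoflurane replicate 1 (503 of the 521 such cells), above the level in every control library.

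For the higher FKBP5 in sevoflurane microglia-like cells, free RNA of the suspension would raise the gene alike in every class. The excess over control was at least 151 times that in GABAergic neuron-like cells in each sevoflurane library (a ratio below 2 was the prediction). That class barely moved and was deeper (medians of 5429 to 8673 against 1465 to 2089 UMIs), which dilutes free RNA in CPM and enlarges the ratio. Other classes rose more, endothelial-like cells from 122 to 479 CPM. In oligodendrocyte-like cells, at medians of 1551.5 to 2186 UMIs, FKBP5 rose from 42.8 to 96.9 CPM, against 407 to 1928 CPM in microglia-like cells. At like depth the rise was thus not alike, which speaks against free RNA as its only source. Border macrophages hidden in the class are not likely either: their markers reached a median of 2.86% of their level in border macrophage-like cells, with MRC1 at 1601 CPM in those and at 1.18 and 0 CPM in control and sevoflurane microglia-like cells, although STAB1 (948 CPM against 475 and 341 CPM) and CD209 (77.7 CPM against 34.2 and 37.3 CPM) reached 36.0% and 48.1% of that level and SIGLEC1 15.5%. A difference in depth would make the shares of cells with an FKBP5 UMI overlap after thinning, and the gap between the groups stayed at 45.9 percentage points. This restates the rise in CPM, already scaled to depth, and is not separate evidence. Median depths were 1644, 1799.5 and 2047 UMIs in the control and 1465, 1607 and 2089 UMIs in the sevoflurane libraries. The unusual tissue of sevoflurane replicate 3 does not account for it, since the log2 fold change was 2.13 without that library. The values are in line with a response of these cells to the exposure or to anything else that differed between the groups, such as handling, which the labels do not let these samples tell apart.

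For the glucocorticoid response list, which was higher in 4 classes, FKBP5 alone was tested as the source. Members besides FKBP5 were higher over the list alone in microglia-like, astrocyte-like and oligodendrocyte-like cells, but not in endothelial-like cells. At the preset correlation the list passed camera without FKBP5 in 4 of the 4. With an estimated correlation it passed in none (lowest camera adjusted p = 0.0746, in astrocyte-like cells), so these calls on the list do not settle the question. Stress during dissociation in the sevoflurane libraries would likely raise heat shock genes with it, and instead the heat shock list was at or below 0 and lower by camera in 2 of those classes, astrocyte-like and endothelial-like cells; its median log2 was -0.21 in oligodendrocyte-like cells (camera adjusted p = 0.154) and 0.15 in microglia-like cells (adjusted p = 0.898), so for microglia-like cells this explanation stays open. The calls on both lists rest on the preset correlation of camera and were lost with an estimated one (adjusted p = 0.0727 at the lowest for the glucocorticoid list). Among the 9 other splits the smallest unadjusted camera p of this list was 0.00499 in microglia-like, 0.00542 in astrocyte-like, 0.000104 in oligodendrocyte-like and 0.000616 in endothelial-like cells, against 1.76e-06, 9.29e-09, 9.21e-09 and 0.000118 for the real groups. Anaesthesia, handling and time of day may each raise glucocorticoids, and the samples hold no group that separates them.

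For the neuron clusters missing from sevoflurane replicate 3, loss of those cells alone would leave the other neurons in their usual ratio, but clusters 21 and 22 came to 1.75 cells per oligodendrocyte-like cell against at most 0.220 in the other libraries. Another region in the tissue piece would also set its glia apart. In 2 of the 2 classes named for this test, astrocyte-like and OPC-like cells, this library was the farthest from its nearest other (correlations of 0.947 and 0.940). The same held in microglia-like, oligodendrocyte-like and GABAergic neuron-like cells. It did not hold in endothelial-like cells (0.912, against 0.750 for sevoflurane replicate 2) or cluster 11 (0.953, against 0.946 for sevoflurane replicates 1 and 2). Fewer counts also lower such a correlation, and this library held the fewest UMIs in OPC-like (660445) and microglia-like cells (347360). In astrocyte-like cells it held 1706835, not the fewest (1362264). In oligodendrocyte-like (3088489) and GABAergic neuron-like cells (5486471) this library held the most. Beside ZBTB20 and RORB, chosen after their values were seen, the granule cell gene PROX1 stood at 4.89 CPM against 15.3 to 88.3 CPM and the upper-layer gene CUX2 at 258 CPM against 16.2 to 151 CPM, while the pyramidal cell gene WFS1 (12.4 CPM) lay within the range of the others. So did the granule cell genes DSP, TDO2 and NPNT, the upper-layer genes LAMP5 and RASGRF2 and the deep-layer gene TLE4. Other deep-layer genes were split. FOXP2 was the highest of the libraries (90.4 CPM against 22.1 to 42.3 CPM). FEZF2 (26.5 CPM against 32.9 to 52.1 CPM) and SEMA3E (40.3 CPM against 84.8 to 138 CPM) were the lowest. A piece that held more cortex and less hippocampus proper would go with ZBTB20, PROX1, RORB, CUX2 and FOXP2, while FEZF2 and SEMA3E went against more cortex. A mislabelled sample was not tested.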

How the results depend on the processing

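Tests without the oligodendrocyte cluster held by 1 library, of the endothelial lists without the library that stands apart, without FKBP5 in the glucocorticoid list and without the called genes in clustering were chosen only after the data were seen. FKBP5 in microglia-like cells kept its direction and its call under every alternative, with log2 2.13 to 2.33 and adjusted p of 0.000252 to 0.0318 when each library was left out, and 2.26 (adjusted p = 0.0407) with the replicate block. The pairs of equal replicate number did not correlate in microglia-like cells (-0.00, -0.03 and -0.24, against 0.25 for the highest other pair), which gives no sign of pairing there and leaves the design open; in endothelial-like cells they were -0.06, 0.07 and 0.13 (highest other pair 0.19) and in GABAergic neuron-like cells -0.18, 0.06 and -0.20 (0.28). Of the comparisons under alternatives, 357 were labelled the same, 63 moved by over 1.5 times, 3 became stronger, 0 weaker and 12 turned. In these labels the limit of 1.5 times was applied only to counts of changed genes and of lists. Differences of shares were labelled by sign and call alone, and the exact test could call none of them. Those that moved by over 1.5 times without turning are thus among the 357, which do not show that their size held. For single named genes 1649 stayed, 116 were weaker, 86 stronger and 7 turned. The 10% mitochondrial alternative was not run, since no mitochondrial gene was named. In simulated data, drawn without dispersions of single genes or libraries that stand apart, 37% of 2-fold changes were found in microglia-like and 13% in endothelial-like cells.

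The count of changed genes in microglia-like cells (8) was 22 with DESeq2, 114 with no filter, 2 on mean log-normalised values and 1 with the replicate block, and ran from 1 to 11 with a library left out. In astrocyte-like cells (2) it was 37 with DESeq2, 163 with no filter, 0 with the block and 0 to 4 with a library left out. In oligodendrocyte-like cells (2) it was 44 with DESeq2, 60 with no filter, 1 on mean log-normalised values, 1 without the cluster held by 1 library, 0 with the block and 0 to 3 with a library left out. In OPC-like cells (3) it was 17 with DESeq2, 102 with no filter, 0 with the block and 0 to 10 with a library left out. In endothelial-like cells (0) it was 1 with DESeq2 and 235 with no filter. In GABAergic neuron-like cells (0) it was 15 with RLE factors, 206 with DESeq2, 12 with limma-voom, 254 with no filter, 1 at resolution 0.5, 15 at resolution 2, 15 on mean log-normalised values and 0 to 21 with a library left out. In cluster 11 (98) it was 242 with DESeq2, 748 with no filter, 36 with the block and 0 to 230 with a library left out. In all cells together (0) it was 427 with DESeq2 and 1 with limma-voom. The cause was not tested for these counts.

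FKBP5 in GABAergic neuron-like cells was log2 0.86 at resolution 0.5 and 0.24 to 0.65 with a library left out; in cluster 11 it was -0.41 to 0.23 with a library left out. On mean log-normalised values, whose differences are not log2 fold changes, it was 0.0582 and 0.0476 in these classes. The FKBP5 difference between microglia-like and endothelial-like cells ran from -0.019 to 0.69 with a library left out. The lists passing in microglia-like cells (1) numbered 0 with an estimated correlation, 2 with the replicate block and 1 to 4 with a library left out; with an estimated correlation 0 passed in astrocyte-like, 0 in oligodendrocyte-like, 0 in OPC-like, 0 in endothelial-like and 0 in GABAergic neuron-like cells; the number in endothelial-like cells (3) was 5 without the library that stands apart in them. With a library left out, differences of shares ran from -3.86 to 0.786 points in GABAergic neuron-like, -0.0636 to 3.01 in choroid plexus-like, -0.830 to 1.19 in microglia-like, -0.964 to 2.73 in oligodendrocyte-like, -1.16 to -0.349 in OPC-like, -0.841 to -0.0983 in endothelial-like, -0.844 to -0.113 in fibroblast-like and 0.00357 to 0.0587 in border macrophage-like cells; that of border macrophage-like cells was -0.104 with doublets kept and -0.0873 at resolution 2. In microglia-like cells IL18 ran from -0.31 to 0.98, RELB from -0.28 to 0.21 and CST3 from -0.081 to 1.21 with a library left out, and RELB was -0.0150 with limma-voom, -0.0860 at resolution 0.5 and, on the scale of mean log-normalised values, -0.0122. The cause was not tested for these.

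Of the 22 calls on genes taken by the naming rule, FKBP5 and genes named outside the rule not included, 22 held with DESeq2, 22 with no filter, 22 with at least 1000 UMIs, 21 with RLE factors, 17 with limma-voom, 13 on mean log-normalised values, 7 with the block and 1 to 21 with a library left out; none turned.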

Other observations

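The tests on other splits of the libraries in this part were chosen only after the results were seen.

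FKBP5 was also higher in 2 small classes that were not tested. In border macrophage-like cells, the resident macrophages of vessels and meninges, the pooled level was 509 CPM in control (24 cells) and 1565 CPM in sevoflurane libraries (30 cells), with 95% Poisson intervals of 348 to 718 and 1278 to 1899 CPM that cover counting error only. In fibroblast-like cells the pooled level was 245 CPM (209 to 284 CPM, 284 cells) and 657 CPM (583 to 737 CPM, 150 cells). In ependymal-like cells it was 22.5 and 24.0 CPM and in choroid plexus-like cells 0 CPM (16 cells, which allows up to 52.0 CPM) and 42.6 CPM (505 cells). In the unnamed clusters pooled it was 62.0 CPM (54.9 to 69.8 CPM) and 151 CPM (140 to 164 CPM). In glutamatergic neuron-like cells pooled it was 43.9 and 47.4 CPM.

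A glutamatergic neuron-like cluster led by TSHZ2, MLIP and KCNB2 (cluster 15) held 459, 510 and 354 cells in the control and 63, 38 and 13 cells in the sevoflurane libraries. This depended on resolution: at 0.5 the cluster with these genes among its leading ones held 617, 561 and 409 against 89, 39 and 397 cells, so sevoflurane replicate 3 was not low. At 2 the cluster led by these genes held 443, 69 and 305 against 57, 35 and 12 cells, and another cluster held 446 cells of control replicate 2. GFAP, the filament protein of astrocytes, had negative fold changes in classes that should hold little of it, at log2 -1.62 in OPC-like cells (35.9 against 10.7 CPM), -1.49 in GABAergic neuron-like cells (19.3 against 6.71 CPM) and -1.82 in cluster 11 (15.7 against 4.40 CPM). None of these was called. Astrocyte-like cells also made up less of the sevoflurane suspensions, 7.99% against 14.0%.

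The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, so these tests neither exclude a grouping by chance nor show it. The real split called 8 genes in microglia-like cells against 0 at most in the 9 others, 2 against 1 in astrocyte-like, 2 against 0 in oligodendrocyte-like, 3 against 2 in OPC-like cells and 98 against 0 in cluster 11, each with 1 split, the real one, as large. In endothelial-like cells (0 against 0), GABAergic neuron-like cells (0 against 1) and all cells together (0 against 1), 10 of 10 splits were as large. For the number of lists that passed, the real split gave 1 in microglia-like cells against 4 at most in another, with 8 splits as large; 5 against 5 in astrocyte-like cells, with 3; and 4 against 7 in oligodendrocyte-like cells, with 5. It gave 1 against 5 in OPC-like cells, with 9; 3 against 8 in endothelial-like cells, with 6; 2 against 6 in GABAergic neuron-like cells, with 7; and 0 against 6 in cluster 11, with 10. Splits with several times the real number of lists could come from a structure of the samples other than the groups or from correlation between the genes of a list above the preset value. With an estimated correlation 0 lists passed in every split and class, the real split included, so these were not told apart; either bears on every list call in the report.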
